A study of Mus musculus with 8 samples.

How the data were processed

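Total RNA from mouse cells that carry a doxycycline-inducible Runx1 gene (iRUNX1, a Tet-on system) was labelled with Cy3 and hybridised to Agilent 1-colour gene expression arrays, 1 sample per array. Per the labels' protocols, embryonic stem cells formed embryoid bodies for 3.25 days, cells bearing the receptor Flk-1 were sorted, cultured and sorted again, and then grown for 2 days as hemogenic endothelium, the endothelial stage from which blood cells arise. Doxycycline was given overnight at 0.3 µl/ml, the unit in which the labels state the dose. The labels describe 3 independent biological replicates, and the series design text adds that they were measured 2 times without saying what was repeated. How independent the arrays counted as n = 3 are rests on the labels. They add 1 array per group titled technical replicate 4, without saying which replicate's RNA was hybridised again. Groups and replicate numbers were taken from the titles. The 2 technical repeat arrays stayed out of the test, which left 3 uninduced and 3 induced arrays.

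The authors deposited the Feature Extraction output of all 8 arrays, with the processed signal and the median signal as spot intensity on a linear scale and the well-above-background, saturation and outlier flags as columns of 0 and 1. Per the file headers the extraction software was version 10.7.3.1, while the submitters' processing notes name version 10.7.1.1 and limma. The authors also deposited a table of log2 values per spot, whose normalization is not given in the sources used here. Its 8 columns had medians of 5.37, 5.37, 5.38, 5.38, 5.38, 5.36, 5.38 and 5.36, in the table's order, and 75th percentiles between 8.9985 and 8.9993. Over 19751 spots with a log2 median signal above 7 on all arrays, each column was set against each array's log2 median signal. The values were on a log2 scale that rises with signal, and what they were centred on stays unknown. Only 2 columns tracked the array they were named for, and 6 tracked another array. The scanner files were therefore the main source, and the table served as an alternative in both readings.

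Each array held 59305 non-control spots of 55681 probes. Control spots and spots flagged as non-uniform or population outliers (114 to 246 per array) were left out, log2 processed signals were set relative to the array's 75th percentile, and spots of a probe were averaged. No spot was saturated. A RefSeq accession given for the probe named its gene through a table of the GRCm38.p6 assembly, used for names and gene order only. It gave 1 symbol to 26582 probes, several to 0 and none to 29099, of which 16194 are named for a genomic region in mm9, the build in the file headers. A probe was kept if it was well above background on all 3 replicate arrays of at least 1 group, which held for 32856 probes. The brightest kept probe stood for its gene, which gave 14503 genes. Among 915 genes past the threshold, 186 had several kept probes, and for 8 of these the probes differed in sign.

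The groups were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of adjusted p under 0.05. Every adjusted p and standard error (SE) of a gene in the text is from this fit, which had no block, unless another is named. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the bright group's mean against the mean, per array, of the lowest signal among probes well above background or the probe's own signal if higher. That floor is not the limit of detection of every probe. On uninduced replicate 1, Gzmc read -5.94 against a floor of -5.96 and was not well above background. A fold given as "at least" is thus relative to this floor of the processed signal, can be too high, and does not hold for normexp values. Gene lists, 17 in number with 605 entries of which 604 matched a gene of the reference, were fixed before the data were examined. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 17 lists, and again with an estimated correlation and with fry. With an estimated correlation 0 of the 17 lists passed, against 11 with the preset one and 5 with fry. The 5 were blood surface and signalling, macrophage and granulocyte, megakaryocyte and mast cell, cardiac, and amino acid and mitochondrial stress genes. Smooth muscle and mesenchymal genes had an estimated correlation of 0.011, near the preset one, yet their adjusted p went from 0.0194 to 0.246. Cardiac genes had one of -0.037, below the preset one, yet theirs went from 0.0123 to 0.246. The setting thus raised the adjusted p even where the estimated correlation was below the preset one. A miss there therefore does not by itself show that correlation between genes explains a call, and does not set 1 list apart from another.

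The genes named are Runx1, the 10 largest rises and 10 largest falls by fitted value among genes past the threshold that moved the same way in all 3 pairs and have a full gene symbol, and further members of the lists. From each of the 4 lists closest to the question (blood transcription factors, blood surface and signalling genes, endothelial genes, smooth muscle and mesenchymal genes) up to 4 members with the smallest adjusted p were taken, and from each other list up to 2. Where fewer than 2 members passed, the brightest members filled up to 2. Members that complete a count of 5 or fewer are named as well and were chosen after their values were seen. Of the genes these rules select, 2 are not reported here.

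The same replicate number deviated from the group means in the same way in both groups: over the 14503 genes the correlations were 0.65, 0.45 and 0.43 for numbers 1, 2 and 3, against -0.47 to 0.13 for unequal numbers. The numbers therefore pair the arrays, on the evidence of the data and of the titles' shared numbers, although the labels do not say what a number shares. The planned fit had no block, and the fit with the replicate number as a block is given beside a result where it changes the call or moves a count by more than 1.5 times. All 8 arrays lay on 1 slide and in 1 scan, so slide and scan could not be tested.

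On data simulated for this comparison over 14503 genes, 0.5 of each gene's variance was shared within a pair, and 65, 64 and 71 genes were changed by 0.58, 1 and 2 on the log2 scale beside 50 genes shifted by 0.5 as a list. There, the fit without a block called 1.54% of genes changed by 0.58 in the right direction, 20.3% of those changed by 1 and 74.7% of those changed by 2, with 0% of its calls false. The fit with the block called 0%, 3.13% and 80.3% of them, with 6.35% of its calls false. In the data, however, the block raised the count of changed genes from 915 to 2346. The simulation does not reproduce how the block acts there, so its rates need not hold for these data. Alternatives covered background correction, scaling, the filter on dim probes, the handling of several probes, the variance model, each array left out, the technical repeat arrays and the deposited table. The files hold no mean signal, so normexp with an offset of 50 ran on the median signal in place of the planned mean signal. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots. The number of arrays limits the precision of every value.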

Results

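Gene expression was measured in differentiating mouse hematopoietic cells at the hemogenic endothelium stage, without and with overnight induction of Runx1, a transcription factor required for the formation of blood cells from endothelium. There were 3 uninduced and 3 induced biological replicates, and 1 technical repeat array per group. The 75th percentile of the processed signal was 699, 378 and 338 on the uninduced arrays of replicates 1, 2 and 3 and 973, 595 and 543 on the induced ones. Between 55.6% and 70.4% of spots were well above background. Cells given doxycycline without the inducible gene were not analysed here, so each difference is that between cells with and without doxycycline.

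Values are log2 signals relative to each array's 75th percentile. Against the 4 brightest E1A spike-in probes, that percentile was higher on the induced array by 1.20, 0.82 and 1.81 in replicates 1, 2 and 3 (mean 1.28 ± 0.50, SD, n = 3), but by only 0.26 between the 2 technical repeat arrays, so the size of this shift is uncertain. All changes below are therefore relative to the overall signal of an array. Scaled to the spike-ins, a setting chosen after seeing the data, every log2 change would be higher by 1.28, the mean of the 3 replicates.

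The comparison asked which genes change when Runx1 is induced. Granule proteases were among the genes with the largest rises, and 7 of 55 endothelial genes were among those that fell. This endothelial count was 1 to 9 with 1 array left out, and 35 with the replicate number as a block, where 1 rose. Of 14503 genes tested, 601 rose and 314 fell, 915 in all or 6.31%. The count was 534 without the filter on dim probes and 378 to 824 with 1 array left out. At least 2-fold changes were seen in 735, of which 487 rose and 248 fell. All 915 moved the same way in all 3 pairs. With the replicate number as a block, 2346 genes changed (1359 rose, 987 fell), among them all 915, and 1235 of them at least 2-fold. Among the genes that rose, 97 were not well above background on any uninduced array, and 5 of those that fell were so on every induced array. The median log2 change of all genes was 0.09, and 65.7% of the changed genes rose. Median centring moved the median of all genes to 0.25 and the share that rose to 77.1%, and spike-in scaling moved them to 1.36 and 99.3%, with 724 genes that rose and 5 that fell.

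**Figure D1:**
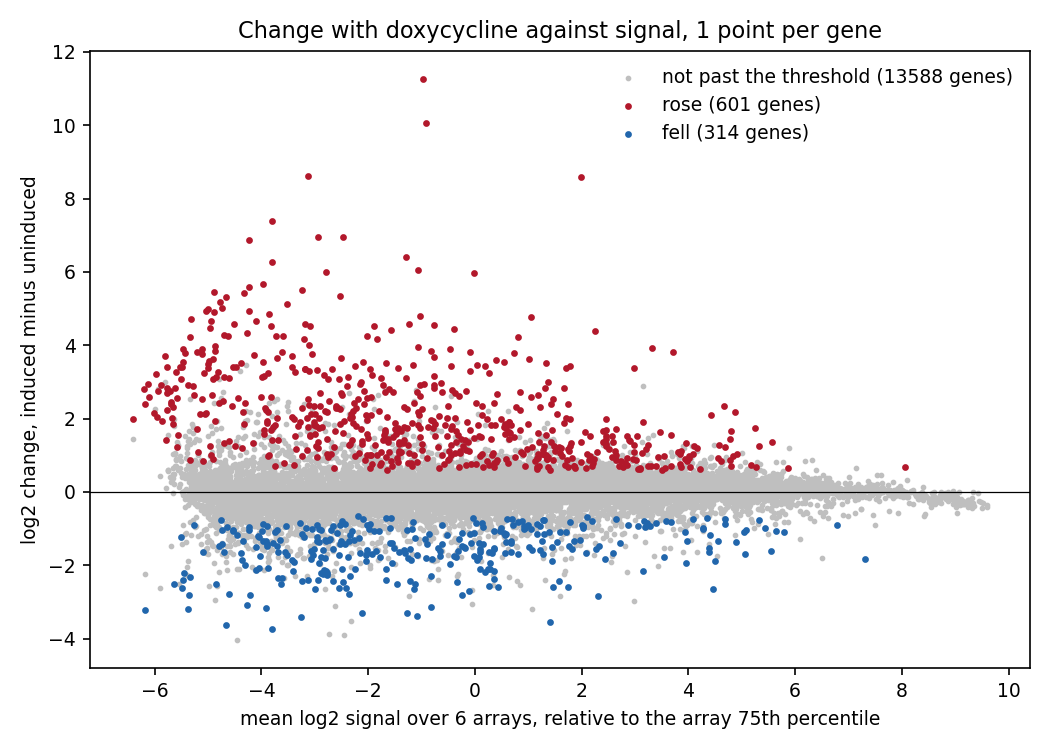
Log2 change (induced minus uninduced) of each tested gene against its mean log2 signal over the 6 arrays, relative to the array's 75th percentile. The 601 genes that rose (red) reach 11.27 and the 314 that fell (blue) reach -3.74 at this scaling; genes not well above background in a group are drawn at their fitted value, which is not a measured fold.

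Runx1 itself was measured by 2 probes. Probe A_55_P2183438 read -4.57 ± 0.25 in uninduced and -5.60 ± 0.60 in induced cells (SD, n = 3), and was well above background on 3 uninduced and 2 induced arrays. The difference was -1.03 (SE 0.32), with an adjusted p of 0.126 in limma and 0.0214 with the replicate block. With spike-in scaling the difference was 0.25. Probe A_51_P206585 was not well above background on any of the 6 arrays. Whether either probe lies in the part of Runx1 that the inducible construct carries is not given in the sources used here, so these values do not check the group labels.

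Among the largest rises by fitted value were those of granzymes and mast cell proteases, serine proteases stored in the granules of cytotoxic lymphocytes and mast cells. Gzmc was at least 1044-fold and Gzmb at least 686-fold higher in induced cells, with adjusted p of 0.000199 and 0.000120 in limma, and neither was well above background on any uninduced array. Gzmd was at least 94.7-fold and Gzmg at least 38.8-fold higher, and Gzme rose by 8.59 (SE 0.46). Gzmd, Gzmg, Gzme and Gzmc are closely similar in sequence, so their probes could share signal and their values are uncertain. Mcpt1 was at least 26.2-fold higher. Mcpt8 rose by 6.96 (SE 0.67, adjusted p 0.00343) and was well above background on 1 of the 3 uninduced arrays. Ccr7, a chemokine receptor of lymphocytes and dendritic cells, rose from -4.50 ± 0.57 to 1.92 ± 0.54 (SD, n = 3), a change of 6.42 (SE 0.37, adjusted p 0.000852). Calm4, a calmodulin-like protein, was at least 60.3-fold higher. Mgp, an inhibitor of calcification in vessel walls and cartilage, was at least 23.8-fold higher. These bounds are relative to the floor of the processed signal only, and the true folds can be smaller. With normexp, whose offset shrinks changes from dim values, the log2 changes were 7.32 for Gzmc, 6.67 for Gzmb, 7.78 for Gzme, 4.19 for Gzmd, 3.00 for Gzmg, 3.70 for Mcpt8, 2.36 for Mcpt1, 4.41 for Ccr7, 3.27 for Calm4 and 2.49 for Mgp.

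The falls reached -3.74. Adora1, an adenosine receptor, fell by 3.74 (SE 0.36, adjusted p 0.00331), and Serpinb1c, a serine protease inhibitor, by 3.63 (SE 0.53, adjusted p 0.0126). They were well above background on 2 and 1 of the 3 induced arrays. Sox17, a transcription factor of arterial and hemogenic endothelium, fell from 3.18 ± 0.64 to -0.36 ± 1.08 (SD, n = 3), a change of -3.54 (SE 0.58, adjusted p 0.0181). Ubd, a ubiquitin-like protein, changed by -3.41, the secreted metalloprotease gene Adamts15 by -3.39, the proapoptotic gene Bik by -3.30 and Tdo2, a tryptophan-degrading enzyme, by -3.17, with adjusted p from 0.000852 to 0.0376. Tdo2 was well above background on 2 of the 3 induced arrays. The homeobox gene Hoxa13 was at least 2.72-fold and the collectin gene Colec10 at least 4.67-fold lower, neither being well above background on any induced array. With normexp the changes were -0.90 for Hoxa13, which no longer passed (adjusted p 0.157), -1.10 for Colec10, -1.86 for Adora1, -1.47 for Serpinb1c, -1.67 for Tdo2, -1.87 for Ubd, -2.38 for Bik, -2.68 for Adamts15 and -3.28 for Sox17. All 9 differences stayed below 0 with spike-in scaling, where only Adora1 (-2.47) and Serpinb1c (-2.36) of the 9 passed the threshold.

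**Figure D2:**
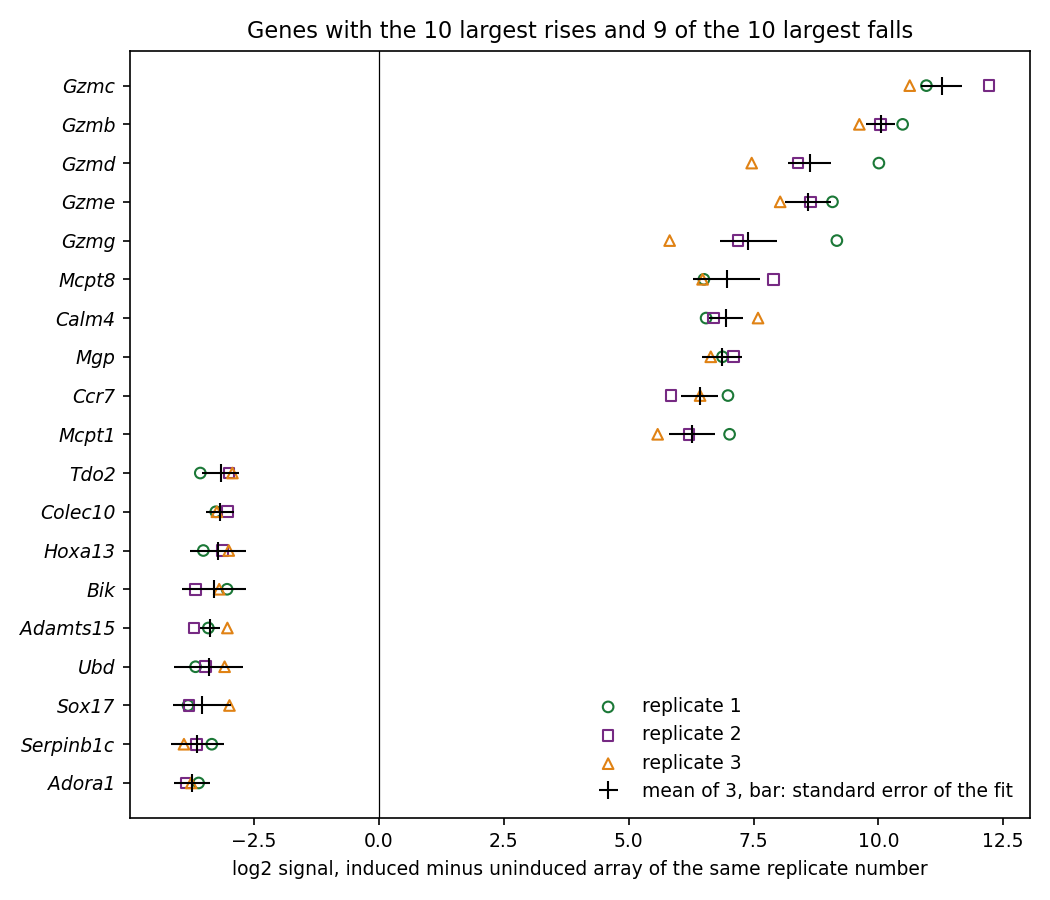
Difference in log2 signal, induced minus uninduced array of each replicate number, for the 10 largest rises and 9 of the 10 largest falls. The bar around the mean of 3 is the standard error of the limma fit without a block. It does not measure the spread of the plotted differences. All 3 pairs lie on 1 side of 0 for every gene, from Gzmc (mean 11.27) to Adora1 (mean -3.74), because the rule that chose the genes requires it. Where a gene is not well above background in a group, the plotted difference is not a measured fold.

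Blood transcription factors were tested as a list of 32 measured genes, of which 8 rose, 0 fell and 24 did not pass. Over arrays left out, 3 to 8 rose, and the list's median ranged from 0.21 to 0.43. Myb, a regulator of blood progenitor growth, rose by 4.79 (SE 0.50, adjusted p 0.00408) and was well above background on 2 uninduced arrays. Ikzf1, needed for lymphoid development, rose by 4.17 (SE 0.46, adjusted p 0.00515), and was well above background on 1 uninduced array. With normexp the changes were 3.38 for Myb and 1.82 for Ikzf1. Cebpe, a factor of granulocyte maturation, was at least 6.996-fold higher (adjusted p 0.00639), but changed by 0.89 with normexp, where it did not pass (0.145). Gfi1, a repressor active in early blood cells, rose by 3.37 (SE 0.51, adjusted p 0.0145). Adjusted over the list alone, 12 rose and 1 fell. The list's median was 0.24, with an adjusted p of 0.0153 in camera and 0.449 with an estimated correlation. With the replicate block 11 rose and 4 fell, and the adjusted p was 0.0815.

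Of 46 blood surface and signalling genes, 15 rose, 0 fell and 31 did not pass. Over arrays left out, 7 to 13 rose. Alox5, which starts leukotriene synthesis, rose by 4.57 (SE 0.45, adjusted p 0.00363). Spn, the leukocyte sialophorin CD43, rose by 4.51 (SE 0.39, adjusted p 0.00275). The integrin gene Itgb3 rose by 3.91 (SE 0.28, adjusted p 0.00167), and Was, an actin regulator of blood cells, by 1.86 (SE 0.21, adjusted p 0.00569). With normexp Alox5 changed by 3.30 and Spn by 2.83. Adjusted over the list alone, 20 rose and 1 fell. The median was 0.61, with an adjusted p of 0.000195 in camera, 0.246 with an estimated correlation and 0.00999 with fry. The replicate block gave 23 that rose and 2 that fell.

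Of 55 endothelial genes, 0 rose, 7 fell and 48 did not pass. Leaving out 1 array gave 1 (without uninduced replicate 2) to 9 (without uninduced replicate 1) that fell. Edn1, which encodes the vasoconstrictor endothelin, fell by 1.46 (SE 0.21, adjusted p 0.0125). Ecscr, a cell surface protein of endothelium, fell by 1.36 (SE 0.18, adjusted p 0.0092). Arhgap29 fell by 1.00 (SE 0.18), and Eng, a coreceptor for TGF-beta, by 0.92 (SE 0.16). Under spike-in scaling Arhgap29 and Eng changed sign, to 0.28 and 0.36. Adjusted over the list alone, 0 rose and 12 fell. With the replicate block 1 rose and 35 fell. The median was -1.16, and 0.11 with spike-in scaling, where 0 members fell. Its adjusted p was 4.17e-12 in camera but 0.361 with an estimated correlation, which was 0.65 for this list, and 0.161 with fry. In the fit with the block the estimated correlation was 0.20, and the adjusted p in camera with it was 0.289.

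Of 39 smooth muscle and mesenchymal genes, 2 rose, 1 fell and 36 did not pass. Mgp rose as given above, S100a4, a calcium-binding protein of motile cells, rose by 1.36 (SE 0.24, adjusted p 0.0245), and Thy1, a surface protein of fibroblasts and lymphocytes, fell by 1.65 (SE 0.35, adjusted p 0.0447), but did not pass with normexp (-0.79, adjusted p 0.149). Adjusted over the list alone, 2 rose and 2 fell, and with the replicate block 6 rose and 9 fell. The median was -0.25 and the mean -0.07, while with spike-in scaling the median was 1.03. The adjusted p was 0.0194 in camera, 0.246 with an estimated correlation and 0.102 without induced replicate 3.

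Among lists of other blood cells, macrophage and granulocyte genes numbered 27, of which 9 rose, 1 fell and 17 did not pass. Ncf1, a subunit of the phagocyte oxidase, rose by 4.51 (SE 0.30, well above background on 2 uninduced arrays, 2.16 with normexp), and Fcer1g, a signalling chain of Fc receptors, by 2.79 (SE 0.28). The 1 that fell was Csf1r, the macrophage growth factor receptor (-1.33). Adjusted over the list alone, 14 rose and 2 fell, and with the block 14 rose and 4 fell. The median was 1.104, with an adjusted p of 0.00582 in camera, 0.246 with an estimated correlation and 0.00999 with fry. With normexp background correction the median was 0.03 and the adjusted p 0.0694. Of 28 megakaryocyte and mast cell genes, 9 rose and 0 fell, among them Mcpt4 (5.34, SE 0.48, well above background on 1 uninduced array, 2.89 with normexp), Itgb3, Gzmb, Mcpt1 and Mcpt8. Mcpt1, Mcpt2, Mcpt4, Mcpt8 and Gzmb, which all rose, lie in a single run of neighbouring genes on chromosome 14, so their rises need not be independent. When adjusted over the list alone, 12 rose and 1 fell, and with the block 16 rose and 3 fell. The median was 1.09, with an adjusted p of 0.000761 in camera, 0.246 with an estimated correlation and 0.00543 with fry. In camera it was 0.233 when genes had to be well above background on all 6 arrays. Of 25 red cell genes, 1 rose and 1 fell, also when adjusted over the list alone. The erythroid and megakaryocyte factor Nfe2 rose by 3.63 (SE 0.59). With the block 1 rose and 8 fell. The median was -0.50, and 0.77 with spike-in scaling, with an adjusted p of 0.0384 in camera, 0.576 with an estimated correlation and 0.422 without uninduced replicate 2. This list also missed the threshold with normexp (0.0674), that stricter filter on all 6 arrays (0.0796) and the technical repeats averaged with number 2 (0.0847), and without induced replicate 1 (0.249) or uninduced replicate 3 (0.0745).

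Lists of other cell types in such cultures were tested as well. Of 19 arterial and Notch genes 0 rose and 2 fell, Sox17 and the Notch ligand Jag1 (-1.67, SE 0.17), also when adjusted over the list alone, and with the block 1 rose and 6 fell. The median was -0.45, and 0.82 with spike-in scaling, with an adjusted p of 0.00582 in camera, 0.442 with an estimated correlation, 0.0581 without a filter and 0.0854 without uninduced replicate 3. Of 18 cardiac genes 0 rose and 2 fell, the troponin gene Tnnc1 (-1.58, SE 0.29) and the heart field factor Hand2 (-1.35, SE 0.26). When adjusted over the list alone, 0 rose and 4 fell, and with the block 0 rose and 6 fell. The median was -0.22, and 1.06 with spike-in scaling, with an adjusted p of 0.0123 in camera, 0.246 with an estimated correlation and 0.00999 with fry. Of 15 epithelial and endoderm genes 2 rose, the endoderm factor Foxa2 (2.58, SE 0.28) and the cadherin gene Cdh1 (2.27, SE 0.34, 1.15 with normexp), and Sox17 fell. With p adjusted over the list alone, 2 rose and 5 fell. The median was -0.35, and 0.92 with spike-in scaling. The adjusted p was 0.0574 in camera and 0.361 with an estimated correlation, and with the block, under which 2 rose and 4 fell, it was 0.0489 and 0.289. Of 14 pluripotency genes 1 fell, Klf4 (-1.35, SE 0.16), also when adjusted over the list alone, while 2 fell with the block. The median was -0.05, but 0.04 with quantile normalization, 0.11 with median centring and 1.22 with spike-in scaling, and the adjusted p was 0.346 in camera. The brightest other member, Klf2, differed by -0.61 (SE 0.18), with an adjusted p of 0.122 and of 0.0431 with the block.

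Of 50 cell adhesion and cytoskeleton genes, 1 rose, 4 fell and 45 did not pass. Tln2, which links integrins to actin, rose by 2.72 (SE 0.28, 2.03 with normexp), although its probes ranged from 0.49 to 2.72. The adhesion receptor gene Icam1 fell by 1.64 (SE 0.24), as did Vcam1 (-2.84), Itga1 (-1.16) and Itga3 (-0.82). When adjusted over the list alone, 1 rose and 5 fell, and with the block 2 rose and 12 fell. The median was -0.26, and 1.01 with spike-in scaling, with an adjusted p of 0.000555 in camera and 0.246 with an estimated correlation. Of 42 proliferation genes 0 rose and 0 fell in limma, also when adjusted over the list alone, and 3 rose with the block. The brightest members were Birc5 (0.33, SE 0.15) and Rrm2 (0.13, SE 0.16). The median was 0.38, with an adjusted p of 9.89e-05 in camera, 0.361 with an estimated correlation and 0.0549 with spike-in scaling.

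The remaining lists did not pass in camera. Of 30 TGF-beta and BMP response genes 5 rose, the ligand gene Tgfb3 (1.98, SE 0.19), Ltbp1, which stores TGF-beta in the matrix (1.99, SE 0.28), Atoh8, Bmp2 and Bmp4, while Eng fell. There were 6 that rose and 1 that fell when adjusted over the list alone, and 5 and 4 with the block. The median was -0.01 and the mean 0.15, camera pointed down (adjusted p 0.963) and fry up, and the median was 0.16 with median centring and 1.27 with spike-in scaling. Of 32 amino acid and mitochondrial stress genes 3 rose, Vldlr, a lipoprotein receptor (3.69, SE 0.37, 2.88 with normexp), Cebpb and Slc7a5, and the stress factor Atf3 fell (-1.47, SE 0.23). When adjusted over the list alone, 5 rose and 1 fell, with an adjusted p of 0.0574 for the list and 0.246 with an estimated correlation, and with the block 6 rose and 2 fell. Of 30 interferon response genes 4 rose, Ifitm1 (3.39, SE 0.39), the interferon factor Irf1 (1.30, SE 0.15), Gbp3 and Usp18, and Ifit3 fell. When adjusted over the list alone, 5 rose and 1 fell, with a median of 0.17 that turned to -0.08 with normexp and an adjusted p of 0.600 for the list, and with the block 6 rose and 2 fell. Of 30 hypoxia and glycolysis genes 3 rose, the vasodilator gene Adm (3.52, SE 0.34), Ndrg1 (1.67, SE 0.24) and Egln3, and 0 fell. Once adjusted over the list alone, 4 rose and 0 fell, with an adjusted p of 0.336 for the list.

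**Figure D3:**
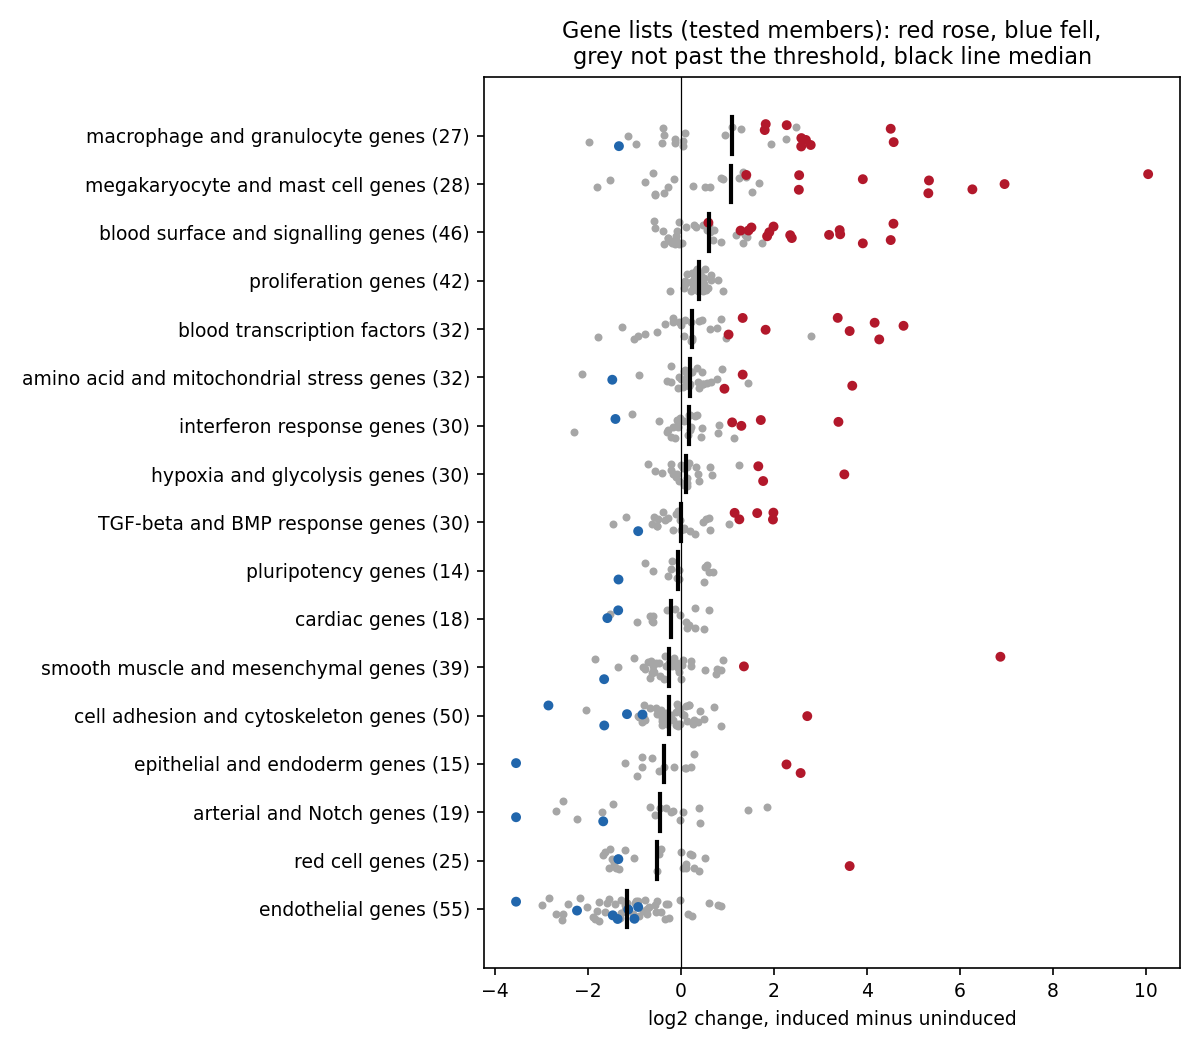
Log2 change (induced minus uninduced, relative to the array's 75th percentile) of each tested member of the 17 gene lists, with the number tested in brackets. Members that rose are red, those that fell blue, others grey, and the black line is the median, which runs from -1.16 for endothelial genes (0.11 with spike-in scaling) to 1.104 for macrophage and granulocyte genes (0.03 with normexp).

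The technical repeat arrays were compared with the replicates over the tested genes. The uninduced repeat differed from replicates 1, 2 and 3 with an SD of 0.61, 0.44 and 0.42 on the log2 scale, beside 0.47 to 0.73 between these replicates. The induced repeat differed from replicates 1, 2 and 3 by 0.85, 0.87 and 0.67, beside 0.49 to 0.61 between the induced replicates. The induced repeat thus lay farther from each induced replicate than these lay from one another, and the array that it repeats could not be told from its values.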

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

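The tests of splits of the arrays were planned, and the 2 results here come from data that the comparison of named genes leaves out. Probes with no gene name in the reference used here were tested in the same way: of 9696 such probes or regions, 116 changed, 71 upward and 45 downward, and 235 changed with the replicate block. They include 38 of 3311 genomic regions (23 rose, 15 fell), named here after their values were seen. On chromosome 12 of mm9, 5 regions on the forward strand between 110842149 and 110940553 fell by 2.18 to 2.89 on the log2 scale. Some of them overlap, so they are not separate loci. A further region on that strand, from 110973190 to 110987668, fell by 1.54. On chromosome 3, the region from 137742666 to 137744470 on the forward strand rose by 5.70 (SE 0.76, adjusted p 0.0205). On chromosome 8, the regions from 67550064 to 67560987 and from 67552315 to 67561235 on the reverse strand rose by 4.26 and 4.70, and that from 67542714 to 67561694 rose by 2.54 on the forward strand and at least 1.34-fold on the reverse strand. No genome of that build was used, so genes and exons at these positions are not given. With spike-in scaling each of these changes would be higher by 1.28.

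The technical repeat arrays stayed out of the comparison. For 896 of the 915 changed genes (97.9%), the difference between the induced and the uninduced repeat array had the direction of the fit. The slope of that difference on the fitted change was 0.98. Which replicates these arrays repeat is not given in the labels, so this is no independent sample.

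The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 915 changed genes, 735 at least 2-fold and 116 unnamed probes, and the highest of the other splits gave 0 each, so 1 of 10 splits reached the real value. Among the 4 splits that part all 3 pairs, the other 3 gave 0 genes with the block, against 2346. The number of gene lists past the threshold in camera was 11 in the real split and 10 in the highest of the others, again reached by 1 of 10. For single lists, adjusted p as small as the real one were given by 3 splits for blood transcription factors (smallest other 1.78e-07), 2 for blood surface and signalling genes (3.86e-06), 2 for endothelial genes (1.42e-25) and 3 for smooth muscle and mesenchymal genes (0.0149), the real split included. Other splits of these arrays thus also gave list calls at the preset correlation. Each of them mixes the groups unequally, so part of the real difference remains between its sides and part adds to the spread within them. Neither their list calls nor their 0 changed genes therefore measure what chance alone would give.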

How the results depend on the processing

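All tests here were planned except those with slide rows, spike-in scaling, the matched table columns and unnamed probes added, which were chosen after seeing the data. No cause was tested unless named. Against 915 changed genes (735 at least 2-fold), the count was 534 without a filter on dim probes, 2346 (1235 at least 2-fold) with the replicate block, 1624, 1620 and 1584 with the technical repeats averaged with number 1, with number 2 and as an added sample, and 341 (341) on row 1 of the slide alone, which has fewer arrays. Normexp gave 482 genes at least 2-fold, and 25 of the 915 had the other sign under it, 0 of them past the threshold. Leaving out 1 array gave 378 to 824 genes (378 to 719 at least 2-fold): 568 without induced replicate 1, 378 without uninduced replicate 2, 506 without induced replicate 2, 547 without uninduced replicate 3 and 571 without induced replicate 3. Slide rows as a block gave 1018, spike-in scaling 729, of which 470 are among the 915, and testing unnamed probes together with the genes gave 751. A slide block was not run because 1 slide held all arrays.

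Runx1 (-1.03) passed with the replicate block and the slide row block (both -1.03), with the technical repeat averaged with number 1 (-0.90) and without induced replicate 3 (-1.35, range -1.35 to -0.76 over arrays left out). It was smaller and did not pass with normexp (-0.62, adjusted p 0.242) and with the matched table columns (-0.54, adjusted p 0.360). Blood transcription factors missed the threshold on the strict filter, well above background on all 6 arrays (adjusted p 0.233), with the block (0.0815), an estimated correlation (0.449) and fry (0.0694), with a range of 0.000496 to 0.147 over arrays left out (0.147 without uninduced replicate 1, 0.0814 without induced replicate 2). Blood surface and signalling genes missed it with an estimated correlation (0.246), and the endothelial list with that (0.361) and fry (0.161). Smooth muscle and mesenchymal genes missed it with normexp (0.0756), no filter (0.105), spike-in scaling (0.323), an estimated correlation (0.246) and fry (0.398), with a range of 0.00786 to 0.102 over arrays left out (0.0509 without uninduced replicate 2). The 13 other lists gave 7 calls, and 5 to 8 over arrays left out. The block changed 1 further list's call (epithelial and endoderm genes, 0.0489) and those of Klf2 and Dlk1, and no other call of a gene or list named here. Amino acid and mitochondrial stress genes passed with normexp (0.0213), no filter (0.00721), the strict filter (0.0281), the slide row block (0.0462), row 1 alone (0.0398), fry (0.00851) and without induced replicate 1 (0.0362), but not with an estimated correlation (0.246). Epithelial and endoderm genes also passed with median centring (0.0352), the slide row block (0.0471), the technical repeats averaged with number 1 (0.0137) or as an added sample (0.0391) and without uninduced replicate 1 (0.0182). Macrophage and granulocyte genes missed the threshold with the strict filter (0.394). The smallest SD of the technical repeats, 0.42 uninduced and 0.67 induced, became 0.30 and 0.55 with normexp and 0.63 and 0.79 without a filter.

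With the value table's columns as named, 0 genes changed (0 at least 2-fold), endothelial genes pointed up (adjusted p 1.93e-06), smooth muscle genes had an adjusted p of 0.721 and 3 other lists passed. By the labels of the scanner files, the columns mix the groups. Matched to arrays, the table gave 929 genes, 813 of them among the 915. As named, these log2 changes had the other sign: Gzmc -0.14, Gzmb -0.44, Gzmd -0.23, Gzme -1.11, Gzmg -0.84, Mcpt8 -0.67, Ccr7 -0.024, Mcpt1 -0.60, Adora1 0.72, Sox17 0.33, Ubd 0.20, Bik 0.33, Alox5 -0.019, Itgb3 -0.18, Was -0.020, Edn1 0.11, Arhgap29 0.23, Eng 0.22, Thy1 0.37, S100a4 -0.32, Jag1 0.25, Mcpt4 -0.76, Tnnc1 0.056, Foxa2 -0.0028, Cdh1 -0.20, Tln2 -0.21, Icam1 0.028, Ltbp1 -0.43, Tgfb3 -0.18, Atf3 0.027, Adm -0.13 and Ndrg1 -0.40. With spike-in scaling Arhgap29 was 0.28 and Eng 0.36. Of 1269 values of the single genes other than Runx1 under 23 alternatives, 1109 kept direction and side of the threshold, 125 missed it, 1 passed it and 34 reversed. Signal near background limits 97 of the genes that rose and 5 of those that fell to a bound.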

Other observations

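All tests of explanations in this part were chosen after results were seen, those of neighbouring genes once the values around Gzmb, Calm4 and Meg3 had been seen, though before the pairs were counted. Changed genes often lay next to each other in the genome, and 11 runs of at least 3 neighbouring tested genes changed the same way. The longest held 11 genes on chromosome 14, all of which rose: Mcpt1, Mcpt2, Mcpt4, Mcpt8, Ctsg, Gzme, Gzmd, Gzmg, Gzmn, Gzmc and Gzmb, proteases of mast cells, granulocytes and cytotoxic lymphocytes. Within it, the smallest fitted log2 change was 1.83 (SE 0.32), for Ctsg. Gzmc had the largest fitted change, at least 1044-fold relative to the floor of the processed signal, and a log2 change of 7.32 with normexp. The calmodulin-like genes Calml3, Calm4 and Calm5 on chromosome 13 were at least 1.94-fold, 60.3-fold and 8.80-fold higher by the processed signal. The receptor genes Adgrg5, Adgrg1 and Adgrg3 on chromosome 8 rose together, Adgrg3 by 3.82 (SE 0.15) and Adgrg1 by 3.43 (SE 0.46). The chemokine genes Ccl9, Ccl6 and Ccl3 on chromosome 11 rose by 3.45, 2.94 and 2.28.

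Runs of genes that fell were found on chromosome 12. Serpina3f, Serpina3h and Serpina3i, protease inhibitors, changed by -2.43, -1.76 and -2.69. The noncoding genes Meg3 (-1.61, SE 0.32, adjusted p 0.0341), 6430411K18Rik (-1.67, SE 0.31, adjusted p 0.027) and Mirg (-1.78, SE 0.23, adjusted p 0.0082) lie next to each other in an imprinted domain. Dlk1, the protein-coding gene beside them that is expressed from the other parental chromosome, differed by -0.97 (SE 0.32), with an adjusted p of 0.146 and of 0.00806 with the replicate block. All of these stay below 0 with 1.28 added for spike-in scaling except Dlk1, and none was called at that scaling.

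Over all 14481 pairs of neighbouring tested genes, 90 had both members changed in the same direction, against a mean of 31.6 in 10000 permutations of the calls over genes. Chance placement is argued against by a permutation p of 1e-04, the smallest these permutations can give. Families of similar genes in tandem, whose probes can also share signal, were tested by leaving out neighbours whose symbols share their first 3 letters: 65 of 13518 pairs remained, against a mean of 29.6, with a permutation p of 1e-04. Such families are thus not the whole cause, although families with unlike symbols stay in that count. Overlapping genes and regulation shared by neighbours stay open and were not tested.

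The endothelial list pointed down and 2 blood lists up, while the red cell list pointed down (median -0.50). Without a block, 7 of 55 endothelial genes fell, and 8 of 32 blood transcription factors and 15 of 46 blood surface and signalling genes rose. With the replicate block 35 endothelial genes fell and 1 rose. There, 11 blood transcription factors rose and 4 fell, and 23 blood surface and signalling genes rose and 2 fell. None of these lists passed camera with an estimated correlation (adjusted p 0.361, 0.449 and 0.246, and 0.576 for red cell genes), where no list did. With fry only blood surface and signalling genes passed (0.00999, against 0.161 for endothelial genes, 0.0694 for blood transcription factors and 0.583 for red cell genes). Scaling as the cause of the endothelial shift relative to other genes is argued against by the settings that do not move all genes alike, since the list's median minus that of all genes was -1.29 with quantile normalization and -1.09 with normexp, but a fall in absolute terms cannot be told apart from the scaling, because the median was 0.114 with the spike-ins. A smaller share of endothelial cells alone would raise the markers of the other cell types alike only if endothelial cells did not express them. Bulk RNA cannot show whether they did. The median of megakaryocyte and mast cell genes exceeded that of smooth muscle and mesenchymal genes by 1.36 (SD over 3 pairs 0.23), and by 1.11 with normexp. Members such as Mcpt1 and Gzmb were not well above background on any uninduced array, and both lie in the run on chromosome 14 given above. With genes well above background on all 6 arrays, the list missed the threshold (adjusted p 0.233 in camera), and the gap was not computed. A smaller share alone is thus not excluded. The megakaryocyte and mast cell list was added after the macrophage and granulocyte list had been tried first and its gap to smooth muscle genes (mean over pairs 1.36, SD 0.22) had been seen to shrink to 0.272 with normexp, so for macrophage and granulocyte genes the smaller share cannot be told apart. A larger share of blood cells may add to the pattern and cannot be told apart from more RNA per cell in bulk RNA, as the blood surface and signalling genes had a median of at least 0.589 in each pair, and a change of state on Runx1 induction stays open, untested.

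In the deposited value table, 6 of 8 columns tracked another array than the one they are named for, with r from 0.9982 to 1.00 against 0.948 to 0.989 for their own array. Among them, 2 columns named for induced cells tracked uninduced arrays and 2 the reverse. One candidate explanation is that the values were listed with all uninduced arrays first and all induced arrays after, under names that alternate: 8 of 8 columns tracked the array at their place in that order. Scanner files placed under the wrong samples are argued against, since the slide position in the header matched the position in the labels for 8 of 8 arrays. No biological explanation was tested for this.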
